A study of Mus musculus with 2 samples.

How the data were processed

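The data were single-cell RNA counts from CD45+ cells, the pan-leukocyte surface marker, of mouse spinal cords collected 15 days after induction of experimental autoimmune encephalomyelitis (EAE), a mouse model of multiple sclerosis. The cells came from mice labelled wild-type (WT) and from mice labelled as knockouts (KO) of STAP-1, an adaptor protein of immune cells. Per the labels' protocols, cells of each replicate were stained with a hashtag antibody and pooled, about 32607 cells were loaded onto a BD Rhapsody microwell system, and cDNA was amplified by the TAS-Seq method. The deposited table held whole-number counts per gene and cell, not normalized, for 25999 genes and 29525 cells. Whether these counts are reads or molecules, and which aligner and annotation made them, is not given in the sources used here. The submitters' processing notes name the genome build GRCm38.

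The labels name 4 hashtags, A0301 and A0302 for WT replicates 1 and 2 and A0303 and A0304 for KO replicates 1 and 2. Cells in the table carried A0301 (6943 cells), A0303 (5757), A0304 (5935) or A0305 (6667), and no cell carried A0302. No label gives a group for A0305, so its cells entered no comparison and are described only as values. A further 4223 columns named as doublets in the table were not used. The comparison planned with 2 libraries per genotype was therefore made between 1 WT library and 2 libraries labelled KO, where a library means the cells of 1 hashtag. The lone WT library was assumed to vary like the pair labelled KO, which left 1 residual degree of freedom. The labels do not say that replicates were separate animals, so the spread between these samples may be technical. The p-values cover no other spread than this, and it was shared across genes as given below.

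Total counts were 51315953 in WT replicate 1, 48183322 in the library labelled KO replicate 1 and 46410226 in the library labelled KO replicate 2, with medians of 5285, 6067 and 5536 counts per cell. The WT library had a median mitochondrial share of 2.54%, against 1.47% and 1.39%. The upper limit that a count of 0 allows, 3 counts, corresponds to 0.0585, 0.0623 and 0.0646 CPM in these libraries, where CPM is the count scaled by the total count of the library. Intervals on shares are exact Clopper-Pearson binomial 95% intervals and those on CPM are exact Poisson 95% intervals. Both cover counting error only.

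Cells needed at least 200 detected genes, which removed 0 cells, and at most 20% mitochondrial counts, which removed 200. Scrublet, run in scanpy 1.11.5, called 340 of the remaining cells doublets (1.84%), and these were removed. The 18095 retained cells (6767, 5568 and 5760) were scaled to 10000 counts, log-transformed and clustered on 2000 variable genes with 30 principal components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2), which gave 22 clusters. Clusters were named from marker lists set before the data were examined, with at least 3 markers held by a cluster. A lead of at least 2 markers over the next class was added after the clusters were seen. Cluster 12 was left unnamed because it held 2 markers of its best class. The added lead left cluster 17 unnamed, which held 3 markers of its best class and 3 of the next. Cluster 12, led by Mpo and Elane, held 1.57% of WT cells and 1.83% and 2.40% of the cells labelled KO. Cluster 17, led by Ly6i, Ccrl2 and Acod1, held 2.29%, 0.521% and 0.521%. All class names are rebuilt from markers and stand for cells like that type.

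Raw counts were summed per library and class where each library had at least 20 cells. Sums were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 after TMM scaling and its low-count filter, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The test shares spread across genes, with a weight given as prior degrees of freedom. Their median was infinite in T cells, microglia, monocytes or macrophages, dendritic cells and erythroid cells. There SEs and p-values rest on the trend across genes, and each gene's own spread between the libraries labelled KO has no weight. The median was 6.45 in all CD45+ cells and 13.7 in neutrophils. Differences between classes were tested as interactions with the library as a block. The 28 gene lists set before the data were examined were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, for lists with at least 5 tested members. Shares were compared with a two-sided exact permutation test, whose smallest p is 0.333 with 1 library against 2. All fold changes are libraries labelled KO against the WT library.

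Genes were named by a rule set before the data were examined. It took Stap1, then up to 10 genes with the largest change in each direction among those past the threshold with a mean of at least 10 CPM and both libraries labelled KO on the same side of the WT library. Where fewer than 5 passed, the 5 with the smallest p under the same conditions were taken as values that did not pass. Up to 4 members of each list that passed, and a few genes fixed by name, were added. A gene fixed by name in T cells is not reported here. The rule and the lists were set for all cells, T cells, microglia, and monocytes or macrophages, and were extended to neutrophils after the data were seen. In all, 19 sums of classes and clusters were looked at, of which 10 are reported.

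The tests were first checked on simulated counts drawn from the real means and library sizes, with 200 genes changed in each of 5 simulated sets. Changed genes had a mean of at least 10 CPM. The spread was set to edgeR's fitted trend, with no spread particular to a gene and no library effect. In all CD45+ cells (19805 genes) 98.2% of 2-fold and 100% of 4-fold changes were recovered, in T cells (13454 genes) 68% and 97.6%, in microglia (13006 genes) 22.4% and 79.6%, in monocytes or macrophages (10681 genes) 23.6% and 74.4%, and in neutrophils (16103 genes) 98.6% and 100%. Between 4.15% and 5.89% of calls were false. The alternatives were DESeq2 1.42.0, its size factors within edgeR, no low-count filter, a minimum mean of 10 CPM, a stricter cell filter of 500 genes and 10% mitochondrial counts, Scrublet calls kept, equal numbers of cells per library, Leiden resolutions of 0.5 and 2, an estimated inter-gene correlation, the fry test, an edgeR test on cell numbers, and leaving out either library labelled KO. Gene positions were taken from a GENCODE annotation of GRCm38, which gave 1 position for 224 of 227 named genes.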

Results

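Single-cell transcriptomes of CD45+ spinal cord cells were compared between mice labelled WT and mice labelled STAP-1 KO at day 15 of EAE. After filtering, 1 WT library with 6767 cells was set against 2 libraries labelled KO with 5568 and 5760 cells. Summed over retained cells, these held 49707187, 46337579 and 44892056 counts. The cells fell into neutrophils, T cells, microglia, monocytes or macrophages, B cells, NK cells, dendritic cells and erythroid cells.

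The targeted gene was examined first. Stap1 (chromosome 5, 86071746 to 86106125, plus strand, GRCm38, protein coding) has 9 exons in its principal transcript, and its 3' UTR spans 86103759 to 86106125 in the last exon. Stap1 transcripts were detected in every class of every library. In T cells Stap1 stood at 128 CPM in the WT library, 120 CPM in the library labelled KO replicate 1 and 276 CPM in the library labelled KO replicate 2, a log2 fold change of 0.58 ± 0.15 (SE) with an edgeR adjusted p of 0.0678. Without the library labelled KO replicate 2 the log2 value in T cells was -0.16. In microglia the levels were 321, 272 and 358 CPM (log2 fold change -0.02 ± 0.27, adjusted p = 0.995). Neutrophils had 146, 34.98 and 59.0 CPM, and there Stap1 fell by 1.63 on the log2 scale (adjusted p = 4.7e-04). That call was lost with DESeq2 (adjusted p = 0.9997) and without a low-count filter (adjusted p = 0.762). Monocytes or macrophages had 105, 49.7 and 69.6 CPM (adjusted p = 0.361), B cells 197, 91.6 and 73.4 CPM, NK cells 106, 57.1 and 104 CPM, dendritic cells 208, 136 and 219 CPM, and erythroid cells 86.2, 58.9 and 16.7 CPM. In all CD45+ cells the values were 145, 65.9 and 100.4 CPM (log2 fold change -0.66 ± 0.19, adjusted p = 0.0628). The labels do not say which part of the gene was deleted, so transcript from the rest of the gene could remain and its counts would then check nothing. The levels in T cells and microglia went against the label, so these are called the libraries labelled KO, and every direction given here rests on that label.

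**Figure D1:**
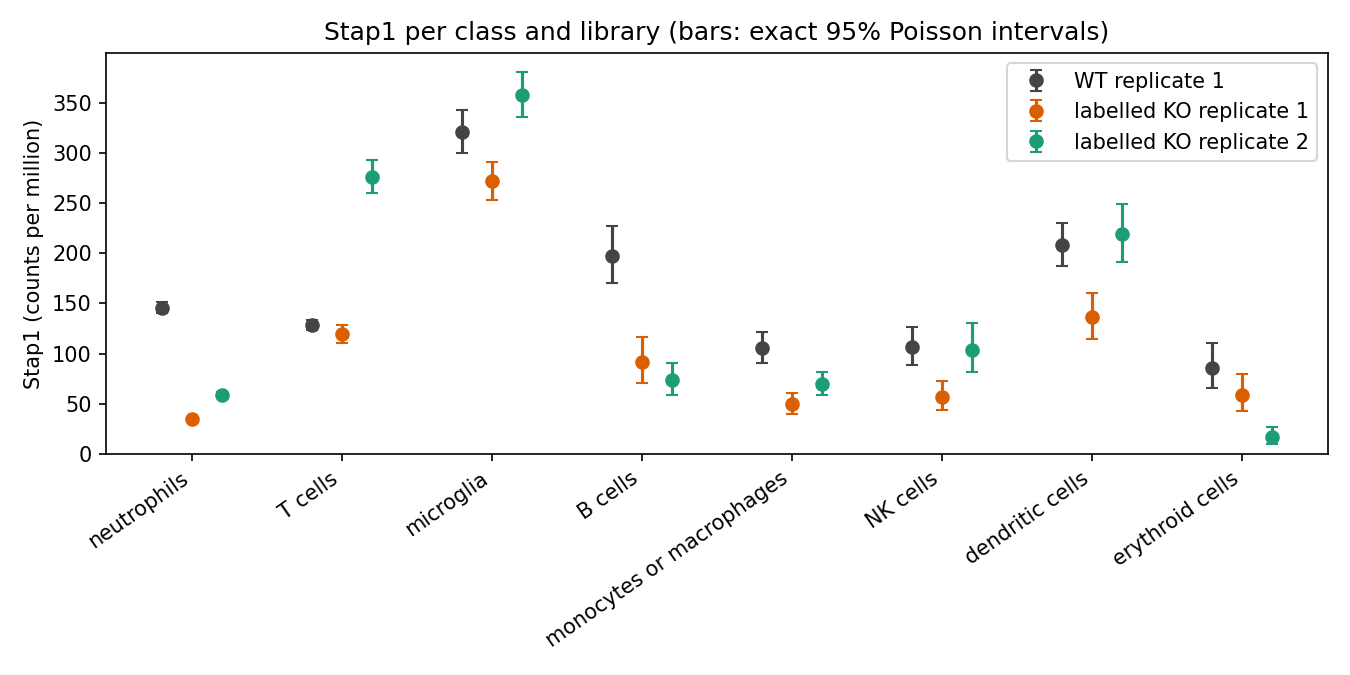
Stap1 in CPM for each cell class (x axis) in the WT library and the 2 libraries labelled KO, as points with exact 95% Poisson intervals that cover counting error only. In neutrophils both libraries labelled KO (34.98 and 59.0 CPM) lay below the WT library (146 CPM), while in T cells the library labelled KO replicate 2 (276 CPM) lay above it (128 CPM).

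The makeup of the CD45+ cells was compared next. T cells made up 42.4% of WT cells (95% interval 41.2 to 43.6), 18.1% (17.1 to 19.1) of the library labelled KO replicate 1 and 11.96% of the library labelled KO replicate 2, a mean of 15.0% ± 4.34 (SD, n = 2) that was 2.82-fold below the WT library (exact permutation p = 0.333, the smallest possible). Neutrophils made up 37.6%, 62.7% and 65.8%. An edgeR test on cell numbers gave an adjusted p of 0.0998 for T cells and 0.133 for neutrophils, so neither share passed a test, and these values go with a label that Stap1 did not bear out in T cells. Microglia, the resident macrophages of the cord, made up 4.73%, 5.51% and 6.48%, monocytes or macrophages 2.36%, 2.80% and 3.85%, NK cells 2.97%, 2.53% and 1.75%, and dendritic cells 2.41%, 1.56% and 1.75%. For dendritic cells the direction reversed at Leiden resolution 2 (0.532%, 0.647% and 0.920%), where cluster 23 (Cd209a, H2-Ab1) was left unnamed. B cells made up 2.78%, 3.25% and 4.25%, but cluster 14 with mature B cell transcripts (Ighd, Fcmr) held most of them in the WT library (2.59% of all cells, against 1.01% and 1.09%), and cluster 13 with early B cell transcripts (Vpreb3) held most in the libraries labelled KO (2.24% and 3.16%, against 0.192%). Erythroid cells made up 0.901%, 1.19% and 1.20%. At Leiden resolution 2 the direction reversed (0.695%, 0.575% and 0.538%). There cluster 9, named neutrophils (Ltf, Ly6g, Ngp), held 63.9%, 66.7% and 58.0% of the cells called erythroid here. With neutrophils, the early B cell cluster, erythroid cells and cluster 12 left out of the denominator, a choice made after seeing the data, T cells made up 71.0%, 56.5% and 43.6%. Among T cells, the cluster led by Foxp3 and Ikzf2, markers of regulatory T cells, held 10.7%, 10.7% and 11.2%, and the cluster led by Cd8a and Cd8b1 held 10.7%, 21.0% and 14.2%.

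**Figure D2:**
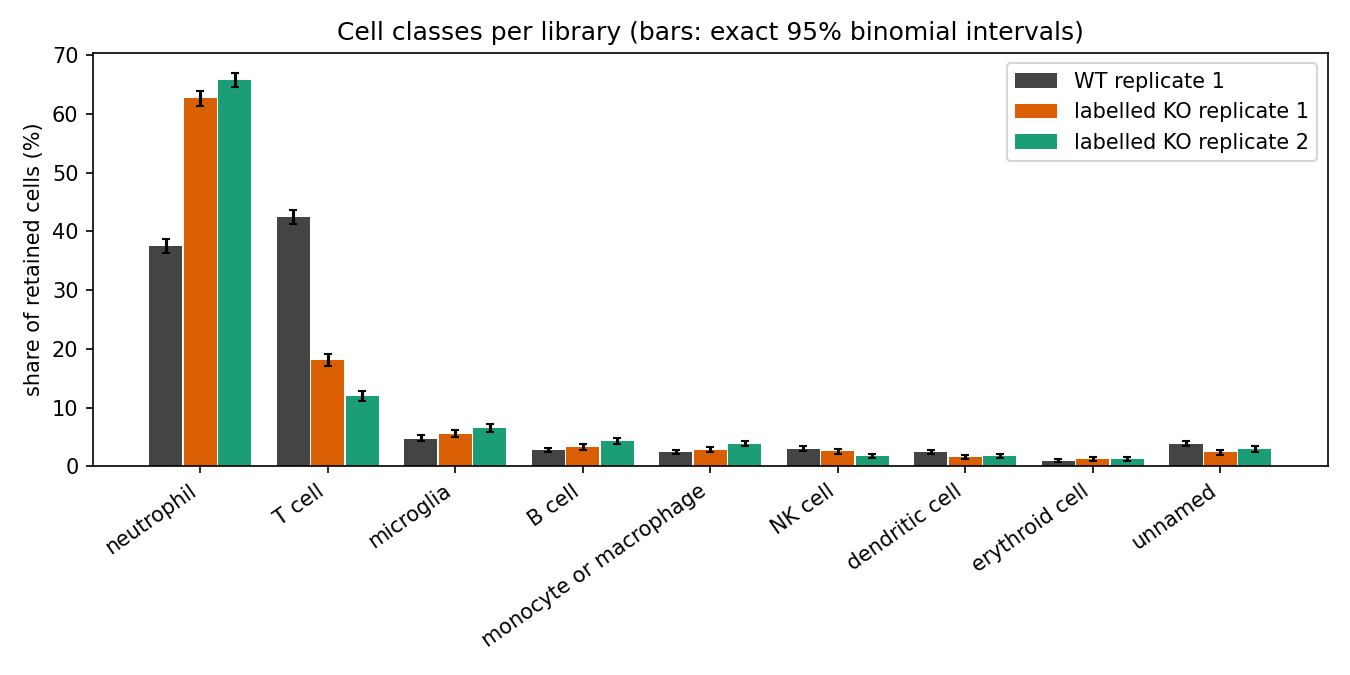
Share of retained cells in each class (y axis, percent) for the WT library and the 2 libraries labelled KO, with exact 95% binomial intervals that cover counting error only. T cells stood at 42.4% in the WT library and at 18.1% and 11.96% in the libraries labelled KO, a difference the exact test could not pass at this size, while neutrophils stood at 37.6%, 62.7% and 65.8%.

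All CD45+ cells, summed, carried lower T cell transcripts and higher transcripts of the early B cell gene Vpreb3 in the libraries labelled KO. Cd5, a T cell surface receptor, fell by 1.66 on the log2 scale (145.8, 47.2 and 36.0 CPM, adjusted p = 0.00241), Cd40lg fell by 1.58 and the adaptor gene Trat1 fell by 1.51. Cxcl9, an interferon-gamma-induced chemokine (chromosome 5, 92321347 to 92328079), fell by 1.53 (48.8, 15.3 and 15.2 CPM, adjusted p = 0.00124). Vpreb3 rose by 2.54 (6.78, 28.6 and 42.9 CPM, adjusted p = 0.00266). The largest increases, Epx (log2 fold change 8.0) and Prg2 (7.11), encode eosinophil granule proteins, and cells with at least 10 Prg2 counts numbered 1 in the WT library, 3 in the library labelled KO replicate 1 and 4 in the library labelled KO replicate 2. The cell with the most counts held 6491 of 12383 Prg2 counts and 1020 of 1508 Epx counts in replicate 1, and 6970 of 7840 and 602 of 676 in replicate 2. Ttr (log2 fold change -4.22) had 5746 of its 5786 WT counts in 1 cell. With edgeR, 1385 genes rose and 1548 fell of 20401 tested, and DESeq2 called 2062, of which 2039 were shared, and 5742 had an unadjusted p under 0.05. With DESeq2 size factors or without a low-count filter edgeR called 0 genes. In these fits the prior degrees of freedom were 2.11 and 1.76, against 6.45 in the main fit.

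Of the 28 lists, 19 passed camera in all CD45+ cells, and none passed with an estimated correlation, where the smallest adjusted p was 0.597. The TCR signalling list fell, with 20 of 24 members lower and 2 higher (the same counts adjusted over the list alone; adjusted p = 1.1e-11, and adjusted p = 0.597 with an estimated correlation), including Cd4 (log2 fold change -1.49) and Cd247 (-1.41). The Treg list fell with 10 of 14 members lower and 12 adjusted over the list alone, including Foxp3 (-1.35), and the Th17 list with 7 of 12 lower and 9 adjusted over the list alone, including Il17re (-1.63) and Il17a (5.13, 1.34 and 1.45 CPM, log2 fold change -1.73). Both had an adjusted p of 0.597 with an estimated correlation. The type II interferon list fell with 15 of 19 members lower and 16 adjusted over the list alone (adjusted p = 0.597 with an estimated correlation). The homeostatic microglia list rose with 8 of 18 members higher and 15 adjusted over the list alone, including Sparc (0.87) and Siglech (0.80), with an adjusted p of 0.613 with an estimated correlation. All 5 red blood cell genes rose, and 5 did so adjusted over the list alone (adjusted p = 0.597 with an estimated correlation). The ribosomal protein list fell with 17 of 17 members lower, and 17 adjusted over the list alone (adjusted p = 1.7e-17, and adjusted p = 0.597 with an estimated correlation). The list of mitochondrially encoded genes fell with 8 of 10 lower and 10 adjusted over the list alone (adjusted p = 3.7e-06, and adjusted p = 0.597 with an estimated correlation). Neutrophil marker RNA made up 13.3%, 21.1% and 20.6% of counts and T cell marker RNA 0.372%, 0.157% and 0.105%.

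T cells of the libraries labelled KO had higher transcripts of the chemokines Ccl5 and Xcl1 and of the interferon-induced Ifit3. Ccl5 (chromosome 11, 83525778 to 83530518), a chemokine of effector T cells, rose by 0.60 on the log2 scale (1155, 2091 and 1476 CPM, adjusted p = 9.0e-13), Xcl1, another chemokine of cytotoxic lymphocytes, rose by 1.43 (adjusted p = 6.3e-05), and Ifit3 rose by 0.94 (72.9, 197.6 and 83.7 CPM, adjusted p = 6.3e-05). Without the library labelled KO replicate 1 the log2 values were 0.29 for Ccl5 and 0.14 for Ifit3. Ccl5 is among the leading genes of the cluster led by Cd8a and Cd8b1, which held 10.7%, 21.0% and 14.2% of T cells, and Xcl1 was more than 5 times higher in NK cells (721 CPM, against 30.7 CPM in T cells). The other named genes that rose were Gh (1.30), Tgfbi (1.20), Il1b (0.96), Retnlg (0.66), Lyz2 (0.52), S100a9 (0.41) and S100a8 (0.37), and beside them neutrophil marker RNA made up 1.11%, 1.45% and 1.45% of T cell counts. Of the 11 genes that rose, 8 were more than 5 times higher in another class, 4 of them highest in neutrophils. Gh was highest in microglia (395 CPM), and Tgfbi and Lyz2 in monocytes or macrophages (822 and 14697 CPM). Of the cytokines and signalling genes fixed by name and given here, none passed. Ifng had 203, 201 and 179 CPM (log2 fold change -0.12), Il17a 13.9, 7.50 and 15.2 CPM (-0.35), Csf2 4.91, 6.34 and 4.74 CPM (0.16), Foxp3 105, 90.2 and 138.8 CPM (0.09), Lck -0.07, Plcg1 -0.18 and Nr4a1 -0.01. Of 14005 genes, 11 rose and 1 fell, and 385 had an unadjusted p under 0.05. With Scrublet calls kept 142 were called, and with equal numbers of cells 26. DESeq2 called 1 gene, and setting the library labelled KO replicate 1 apart in place of the WT library called 49. Changes of 2-fold were recovered in 68% of simulated cases.

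Among T cell lists, 15 of 27 passed camera and 0 passed with an estimated correlation or fry. The chemokine list rose with 1 of 12 members called and 4 adjusted over the list alone (adjusted p = 4.2e-17, and adjusted p = 0.634 with an estimated correlation). The cytotoxic list rose with 1 of 12 called and 5 adjusted over the list alone, and the type I interferon list with 1 of 20 and 4 adjusted over the list alone (adjusted p = 0.634 with an estimated correlation for each). Beside the chemokine and cytotoxic lists, the share of T cells in the cluster led by Cd8a and Cd8b1 stood at 10.7%, 21.0% and 14.2%. Beside the type I interferon list, cluster 19 at Leiden resolution 2 (Ifit1, Ifit3, Mx1) held 5.57% of T cells in the WT library, 11.5% in replicate 1 and 2.90% in replicate 2, so replicate 1 alone lay above the WT library. The list of TCR-induced activation genes fell with 0 of 22 members called by edgeR or adjusted over the list alone (adjusted p = 0.634 with an estimated correlation). Its member Cd5 had 377, 295 and 313.5 CPM. The Th1 list had a median of -0.06 but a mean of 0.03 and an upward test, and the Th17 list a median of -0.13 but a mean of 0.05 and a downward test (adjusted p = 0.634 and adjusted p = 0.642 with an estimated correlation). Red blood cell RNA, 0.0426%, 0.0316% and 0.0280% of counts, fell as a list with 0 of 5 members called by edgeR and 4 lower adjusted over the list alone (adjusted p = 0.634 with an estimated correlation). With equal numbers of cells its members Hba-a1 (0.014), Hbb-bs (0.33), Hbb-bt (0.37) and Hba-a2 (0.52) turned upward. The ribosomal protein list (0 of 17 called by edgeR or adjusted over the list alone, median -0.07, adjusted p = 6.2e-09) and the list of mitochondrially encoded genes (0 of 10, median -0.04, adjusted p = 0.00249) fell beside these, and each had an adjusted p of 0.634 with an estimated correlation.

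Microglia of the libraries labelled KO had lower transcripts of the chemokines Cxcl13 and Cxcl9 and higher transcripts of the homeostatic genes Fcrls and Gpr34. Cxcl13 (chromosome 5, 95956951 to 95961068), the B cell-attracting chemokine, fell by 2.70 on the log2 scale (125.9, 21.9 and 16.4 CPM, adjusted p = 2.2e-14), and Cxcl9 fell by 1.41 (401, 158 and 142 CPM, adjusted p = 9.5e-05). Spp1, the secreted protein osteopontin (chromosome 5, 104435118 to 104441050), fell by 1.87 (adjusted p = 5.7e-04) and the complement gene C2 by 1.64 (adjusted p = 0.00312). The homeostatic genes Fcrls (148, 209.5 and 503 CPM, adjusted p = 0.00385) and Gpr34 (178, 288 and 450.3 CPM, adjusted p = 0.0355) rose by 1.26 and 1.05, whereas P2ry12 (676, 901 and 1607 CPM, adjusted p = 0.0917) and Tmem119 (0.33) did not pass. Without the library labelled KO replicate 2 the log2 value of Fcrls was 0.52. At Leiden resolution 2, cluster 22 (P2ry12, Fcrls, Gpr34) held 16, 42 and 191 microglial cells (5.0%, 13.7% and 51.2% of the class) and cluster 8 (C4b, Apoe, Ccl12) held all others, so different clusters held most of the class in the WT library and in replicate 2. The chemokines Ccl6 (1.30) and Cxcl2 (1.11) rose, but neutrophils held more of both (839 CPM of Ccl6, against 221 CPM in microglia, and 1179 CPM of Cxcl2, against 213 CPM). The T cell genes Ifng (-1.99), Cd27 (-1.66), Tnfrsf9 (-1.54) and Tnfrsf4 (-1.46) fell, and T cell marker RNA made up 0.279%, 0.227% and 0.130% of microglial counts. Granulocyte genes were among the largest increases (Stfa3 5.45, Stfa1 4.72, Olfm4 4.28), and neutrophil marker RNA made up 2.08%, 5.27% and 4.22%. Apoe, H2-Aa and Cxcl10 did not pass (-0.41, -0.67 and -0.27). With edgeR 77 genes rose and 22 fell of 13511, and 51 of the 77 were more than 5 times higher in another class, 44 of them highest in neutrophils. Without such genes, an exclusion chosen after seeing the data, 16 rose and 13 fell. DESeq2 called 28 genes and the stricter cell filter left 17.

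Of 25 lists in microglia 18 passed camera and 0 passed with an estimated correlation or fry. The type II interferon list fell with 1 of 18 members called and 3 adjusted over the list alone (adjusted p = 2.9e-10, and adjusted p = 0.635 with an estimated correlation). The MHC class II list fell with 0 of 12 called by edgeR and 6 adjusted over the list alone, including Cd74 (6763, 4660 and 3971 CPM), and had an adjusted p of 0.635 with an estimated correlation. The homeostatic list rose with 2 of 18 members called and 3 higher and 1 lower adjusted over the list alone (adjusted p = 0.653 with an estimated correlation). The cytotoxic and Treg lists fell with 1 of 12 and 2 of 11 members called, and 5 and 6 adjusted over the list alone (adjusted p = 0.635 with an estimated correlation for each). Most of their members are T and NK cell genes, but the cytotoxic list shares Ccl3, Ccl4 and Ccl5 with the chemokine list. The chemokine list fell with 3 of 16 members lower and 2 higher, and 4 lower and 3 higher adjusted over the list alone (adjusted p = 4.1e-04, and adjusted p = 0.635 with an estimated correlation). The ribosomal protein list (0 of 17 members called by edgeR or adjusted over the list alone, median -0.34, adjusted p = 6.0e-06) and the list of mitochondrially encoded genes (0 of 10, median -0.18, adjusted p = 0.0342) fell beside these, and each had an adjusted p of 0.653 with an estimated correlation. The disease-associated microglia list did not pass (adjusted p = 0.184).

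**Figure D3:**
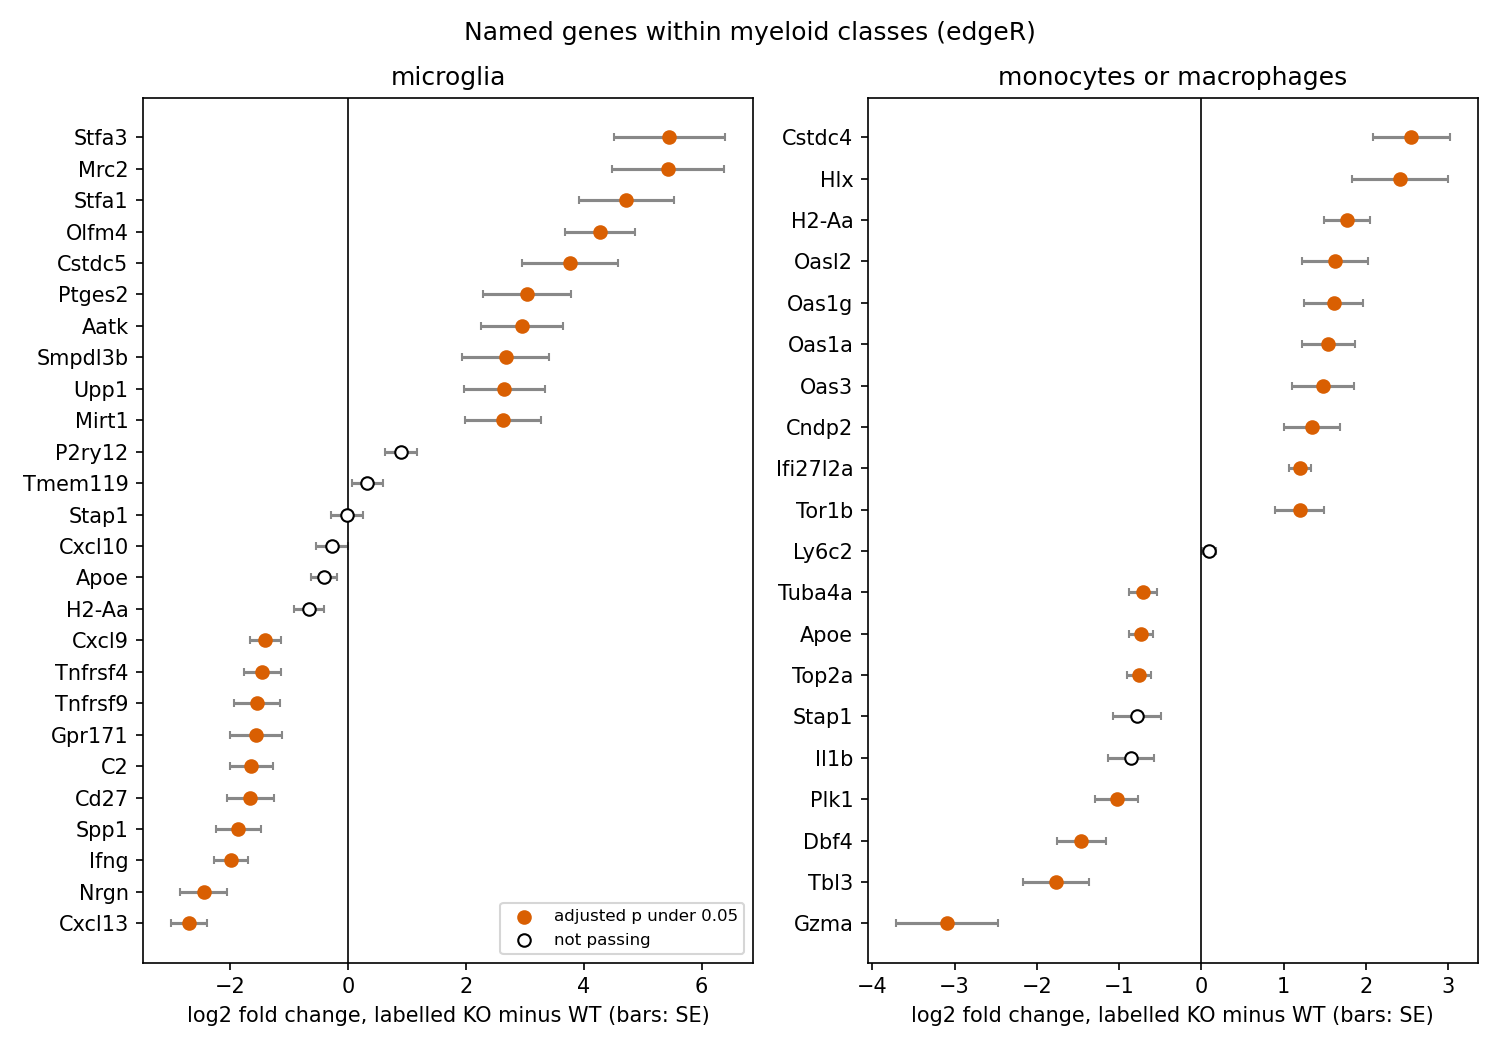
Log2 fold change (x axis, libraries labelled KO against the WT library) with its SE for Stap1, the genes with the largest changes and the genes fixed by name in microglia (left) and monocytes or macrophages (right). Filled points passed the edgeR threshold, among them Cxcl13 (-2.70) and Cxcl9 (-1.41) in microglia and Ifi27l2a (1.20) and H2-Aa (1.77) in monocytes or macrophages.

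Monocytes or macrophages of the libraries labelled KO had higher transcripts of the interferon-induced gene Ifi27l2a and of Oas genes, and lower transcripts of the cell cycle genes Top2a, Plk1 and Dbf4. Ifi27l2a (chromosome 12, 103442167 to 103443680) rose by 1.20 (524, 1191 and 1166 CPM, adjusted p = 1.4e-14). The antiviral genes Oas1a (37.1, 109.6 and 102.6 CPM), Oasl2, Oas1g and Oas3 rose by 1.54, 1.63, 1.61 and 1.47. The MHC class II gene H2-Aa rose by 1.77 (47.1, 198 and 117 CPM, adjusted p = 4.7e-07), but its level in dendritic cells was more than 5 times higher (3587 CPM, against 120.0 CPM). Top2a, a topoisomerase of dividing cells, fell by 0.76 (732, 454 and 395 CPM, adjusted p = 4.4e-04), Plk1 fell by 1.03 and Dbf4 by 1.46. Apoe fell by 0.73 (758, 393 and 501 CPM, adjusted p = 6.6e-04), but its level in microglia was more than 5 times higher (9769 CPM, against 548 CPM). Microglia made up 4.73%, 5.51% and 6.48% of retained cells, and dendritic cells 2.41%, 1.56% and 1.75%, reversed at Leiden resolution 2. At the main resolution neither share moved in the direction of its gene, Apoe or H2-Aa, and carry-over was not tested. Gzma, a granzyme of NK and T cells, fell by 3.10. Ly6c2 (0.09) and Il1b (-0.86) did not pass, and Arg1 and Nos2 were too low to test, with Nos2 at 0 counts. In all 21 genes rose and 7 fell of 11178 tested, and DESeq2 called 1. With equal numbers of cells 3 were called. Of the 21, 9 were more than 5 times higher in another class, 7 of them highest in neutrophils. Of the 7 that fell, 2 were so, Apoe and Gzma, the latter highest in NK cells. Without such genes, an exclusion chosen after seeing the data, 9 rose and 4 fell. Neutrophil marker RNA made up 2.60%, 4.12% and 3.16% of counts.

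In this class 4 of 23 lists passed camera and 0 passed with an estimated correlation or fry. The proliferation list fell with 1 of 18 members called and 9 adjusted over the list alone (adjusted p = 7.7e-12, and adjusted p = 0.864 with an estimated correlation). The type I interferon list rose with 2 of 19 called and 5 adjusted over the list alone, the MHC class I list with 0 of 11 called by edgeR and 4 adjusted over the list alone, and the MHC class II list with 1 of 12 called and 3 adjusted over the list alone. Each had an adjusted p of 0.864 with an estimated correlation.

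Neutrophils, examined in full after the data were seen, had lower transcripts of Stap1 and of several other genes. Slc11a1, a phagosomal metal transporter (chromosome 1, 74375195 to 74386062), fell by 1.16 (71.2, 28.8 and 34.9 CPM, adjusted p = 3.4e-04), Ifitm1 by 0.83 (966, 536.5 and 549 CPM, adjusted p = 1.5e-05) and Wfdc17 by 0.69. Abhd10 fell by 1.51, and the stefin genes Cstdc5 and Stfa1 by 1.11 and 0.80. The stefin genes are members of a family of near-identical copies whose counts are uncertain. At Leiden resolution 2, cluster 5 (Il1b, Wfdc17, Ifitm1) held 12.2%, 8.65% and 10.8% of neutrophils, and cluster 12 (Cstdc5, Stfa2, Cstdc4) 8.06%, 6.30% and 5.83%. Cluster 2, with Wfdc17 and Ifitm1 also among its leading genes, went the other way (11.01%, 12.98% and 13.9%). Whether these shares account for the falls was not tested. The interferon-induced genes Ifi204 (0.96), Ifit1bl2 (0.72) and Ddx60 (0.64) rose, but none of these calls held with equal numbers of cells, where edgeR called 10 genes that fell, and with Scrublet calls kept that of Ifi204 alone held. The proliferation list fell with 0 of 18 members called by edgeR and 12 adjusted over the list alone (adjusted p = 1.6e-20, and adjusted p = 0.867 with an estimated correlation), and the type I interferon list rose with 0 of 20 called by edgeR and 6 adjusted over the list alone (adjusted p = 0.867 with an estimated correlation). Beside them, cluster 11 at Leiden resolution 2 (Top2a, Mki67, Ube2c) held 7.91%, 6.90% and 5.93% of neutrophils, and cluster 17 (Rsad2, Ifit3b, Ifit3) held 3.19%, 4.04% and 3.80%. The list of dissociation stress and immediate early genes also fell by camera and did not pass with an estimated correlation. In neutrophils 3 genes rose and 11 fell of 16625. Of these 1 and 3 were more than 5 times higher in another class, among them Slc11a1 (239 CPM in microglia, against 41.8 CPM) and Ifi204 (182 CPM, against 34.5 CPM). Without a low-count filter edgeR called 0. DESeq2, run without that filter but with its own default filter on mean counts, called 12, so these counts are not like for like. With edgeR's low-count filter 1345 genes had an unadjusted p under 0.05 in edgeR, and Leiden resolutions of 0.5 and 2 gave 89 and 103.

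The remaining classes are given as counts. Of the genes tested, 57 rose and 41 fell in B cells, where different clusters (13 and 14) held most of the class in the libraries compared, 34 rose and 4 fell in NK cells, 105 rose and 123 fell in dendritic cells, where Leiden resolution 2 parted cluster 23 (Cd209a, H2-Ab1; 126, 50 and 45 cells) from cluster 28 (Cox6a2, Ccr9; 36, 36 and 53 cells), and 7 rose and 1 fell in erythroid cells. In T cell cluster 0, which is led by Cd4 and Tcf7, 4 rose and 1 fell. DESeq2 called 71, 11 and 28 genes in B, NK and dendritic cells, 0 in erythroid cells and 0 in T cell cluster 0, where edgeR gave 425 and 241 genes an unadjusted p under 0.05.

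Differences between classes were tested directly. Of 14755 genes, 35 changed differently in microglia and T cells by edgeR. The log2 change in microglia lay above that in T cells for 14 of them and below it for 21, a direction and not a size. With DESeq2 size factors 22 were called. For Ifng the change in microglia minus that in T cells was -1.89 on the log2 scale (adjusted p = 1.2e-04). Between T cells and monocytes or macrophages edgeR called 0 genes of 13583, with 637 at an unadjusted p under 0.05, and no other tool was run on it. Without a low-count filter edgeR called 20, so the 0 depended on the filter.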

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

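The tests of dilution, of a common rise of other classes, of free RNA and of misassigned hashtags were chosen after the results were seen, as was the comparison of T cells with neutrophils. That of other splits of the libraries was written before, and so was that of cell makeup, which was dropped once counts of called genes were known and then run as first written.

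The change between the WT library and the libraries labelled KO differed between microglia and T cells for 35 genes by the edgeR interaction test. For T cell and NK cell genes the change in microglia lay below that in T cells, with log2 differences of -1.89 for Ifng, -2.05 for Cd27, -1.34 for Tnfrsf4, -2.30 for Cd160, -1.22 for Ccl5 and -1.11 for Nkg7. The chemokines Ccl3 (-1.55) and Cxcl9 (-2.28), as well as H2-Ab1 (-1.18), Nrgn (-1.99) and Gh (-1.30), were also lower in that comparison. The haemoglobin genes Hba-a1 (1.67), Hbb-bs (1.61) and Hbb-bt (1.85) and the neutrophil genes Retnlg (1.26) and S100a8 (1.00) were higher. Red blood cell RNA made up 0.0453%, 0.180% and 0.0331% of microglial counts, so of the libraries labelled KO replicate 1 alone lay above the WT library. Between T cells and neutrophils 26 genes differed, and Stap1 had a log2 difference of -2.13. In the cells with hashtag A0305, which no label places in a group, some levels lay above those of the WT library, both before cell filtering. These were, in CPM, Stap1 (263, against 147), S100a8 (53381, against 42739), Ncr1 (11.4, against 6.20), Hbb-bs (1223, against 580) and Gh (156, against 61.4). They were listed because they lay above the WT library. The other genes looked at in these cells lay below it and are given at the end.

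Fewer T cells in the libraries labelled KO formed the pattern a biologist would follow first. Dilution by marrow-like cells was tested by leaving out neutrophils, the early B cell cluster, erythroid cells and the cluster with Mpo. The WT share of T cells then stood 1.26 times above that of replicate 1 (interval from 1.18) and 1.63 times above that of replicate 2, and T cells per other cell, which dilution would leave alike, stood 1.88 times (from 1.60) and 3.16 times (from 2.67) above. A lower share of T cells alone would raise all other classes alike, and the ratios of microglia and mature B cells to their WT shares differed 2.998-fold and 3.24-fold in the 2 libraries. These intervals cover counting error only, the libraries labelled KO differed 1.68-fold from each other in T cells per other cell, and 1 WT library allows no exact p below 0.333, so dilution and a lower share of T cells alone cannot be told apart from genotype, which stays open and untested.

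Stap1 counts in T cells and microglia of the libraries labelled KO were weighed against technical sources. Free RNA taken up alike by all classes would put Stap1 at a like level in each class of a library. Its highest class exceeded its lowest 7.77-fold in replicate 1 and 21.4-fold in replicate 2, beyond counting error. But RNA of other classes was not spread alike. T cell marker RNA made up 0.227% of microglial and 0.0114% of neutrophil counts in replicate 1, and 0.130% and 0.0117% in replicate 2. The range of Stap1 therefore cannot exclude RNA carried over unevenly. Cells of the WT library carrying a KO hashtag could not exceed the WT level, yet T cells of replicate 2 held 2.15 times the WT level, which argues against that source. If such cells came from all WT classes alike, the ratio of Stap1 counts to those of the WT library would be the same in every class, yet in microglia it was 2.63 times that in neutrophils in replicate 1 and 1.92 times in replicate 2, which argues against them as the only source there. In T cells of replicate 1 the level was 0.931 times that of the WT library and the ratio of counts 0.883 times that in neutrophils (0.831 in replicate 2), so misassigned hashtags cannot be told apart from other sources in T cells of replicate 1, since the intervals include the WT level and the ratio in neutrophils, and a deletion that leaves part of the transcript, or a wrong label, was not tested. These tests cover cells of the WT library only. Cells of hashtag A0305 carrying a KO hashtag were not tested, and could exceed the WT level. Over all their classes, before cell filtering, Stap1 stood at 263 CPM, against 147 CPM in the WT library.

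Genes called in all CD45+ cells may reflect a shift in cell makeup between libraries. Within neutrophils and within T cells these genes had a median absolute log2 fold change of 0.125 and 0.152, under the limit set for a shift in makeup. All genes tested in these classes had 0.192 and 0.174, also under it, so that limit decides nothing. In all cells the called genes had 0.627 and 0.628, but they were chosen by their call there. The values show only that these genes changed no more within these classes than other genes did. With 3 splits of the 3 libraries no share under 0.05 is possible. The split that sets the WT library apart called 2933 genes in all cells (highest other split 2), 99 in microglia (4), 28 in monocytes or macrophages (11) and 14 in neutrophils (10), as many in 1 of the 3 splits each, but 12 in T cells, where another split called 49 and 2 of the 3 splits called as many.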

How the results depend on the processing

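The exclusion of genes more than 5 times higher in another class, the exclusion of marrow-like cells and all alternatives in neutrophils except leaving out a library were chosen after the results were seen. No paired analysis was possible because the groups compared share only replicate number 1. Leaving out the WT library leaves no WT cells, and leaving out a library labelled KO leaves 1 against 1 with no test, so these give values for Stap1, named genes and shares only. Of 3305 values under alternatives for 330 results, 2605 kept their direction and call, or their size where there was no test, 348 lost the call, 56 gained one, 285 moved in size and 11 reversed. Where a cause is not stated, the cause was not tested.

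Counts of genes called moved as follows. All CD45+ cells: 0 with DESeq2 size factors and 0 without a low-count filter, against 2933. T cells (12): 1 with DESeq2, 7 with its size factors, 7 at a mean of 10 CPM, 6 with the stricter cell filter, 142 with Scrublet calls kept, 26 with equal numbers of cells, 7 at resolution 2 and 3 without genes 5 times higher elsewhere. Microglia (99): 28 with DESeq2, 17 with the stricter filter and 29 without such genes. Monocytes or macrophages (28): 1 with DESeq2, 3 with equal numbers, 10 and 11 at resolutions 0.5 and 2, and 13 without such genes. Neutrophils (14): 0 without a filter, 28 at 10 CPM, 8 with Scrublet calls kept, and 89 and 103 at resolutions 0.5 and 2. The interaction of T cells with microglia gave 22 with DESeq2 size factors, and that with monocytes or macrophages 20 without a filter. Lists passing went to 0 with an estimated correlation and 0 with fry in all 4 planned classes. Both rest on 1 residual degree of freedom and could pass almost no list, so this decides little.

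Stap1 passed with equal numbers of cells in all cells (-0.64) and T cells (0.72), and in microglia turned to 0.070. In neutrophils it no longer passed with DESeq2 (-1.63) or without a filter (-1.63). Without either library labelled KO it ranged from -0.96 to -0.40 in all cells, from -0.16 to 1.04 in T cells, from -2.04 to -1.31 in neutrophils and from -0.21 to 0.15 in microglia. The dendritic cell share reversed at resolution 2 (0.56). The erythroid share gave 0.26 with Scrublet calls kept, 0.60 with the stricter filter, 0.65 at resolution 0.5 and -0.32, reversed, at resolution 2. The T cell share moved to -0.50 without marrow-like cells. In T cells with equal numbers of cells Hba-a1 (0.014), Hbb-bs (0.33), Hbb-bt (0.37), Hba-a2 (0.52), Ifng (0.016) and Nr4a1 (0.53) reversed, and with Scrublet calls kept Ltb4r1 (0.053) and Foxp3 (-0.037) did. Of simulated 2-fold changes 22.4% were recovered in microglia and 23.6% in monocytes or macrophages, where edgeR's biological coefficient of variation, 0.207 and 0.205, also exceeded that in T cells (0.149) and neutrophils (0.0861). Depth and spread were not separated.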

Other observations

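Among T cells, the cluster led by Ccl1, Nrgn and Ifng held 5.92% in the WT library and 3.57% and 7.55% in the libraries labelled KO. T cells per microglial cell numbered 8.97, 3.28 and 1.85, T cells per NK cell 14.3, 7.15 and 6.82, and neutrophils per microglial cell 7.94, 11.4 and 10.2. In neutrophils the list of dissociation stress and immediate early genes fell (adjusted p = 9.9e-08 by camera, and adjusted p = 0.867 with an estimated correlation). None of its members was among the genes called there by edgeR.

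The 6667 cells with hashtag A0305 held 54957292 counts, with a median of 5906 per cell. Their Cd3e level was 190.2 CPM, against 229 in the WT library and 104 and 67.5 in the libraries labelled KO, all before cell filtering. In the same order, P2ry12 had 40.8 CPM against 41.6, 63.4 and 101, and Ly6c2 1746 CPM against 1749, 2213 and 2178. Cd79a had 41.3 CPM against 46.2, 56.5 and 81.8, and Il17a 4.49 CPM against 4.97, 1.29 and 1.51. Ifng had 76.5 CPM against 85.8, 34.0 and 22.8. These values give the cells no group.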
